A study of Arabidopsis thaliana and Oryza sativa Japonica Group and Zea mays subsp. mays with 4 samples.

How the data were processed

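The data were transcript assemblies from RNA of whole seedlings, 2 weeks old, in 4 samples: wild type Arabidopsis thaliana (Col-0), wild type rice (Nipponbare), wild type maize (B713 in the labels) and the Arabidopsis mutant ddm1 (allele ddm1-10). Per the labels, Arabidopsis and rice were grown on half-strength MS medium and maize on soil. RNA was extracted with Trizol and treated with a DNase kit before library construction with TruSeq Stranded mRNA, a kit that enriches polyadenylated RNA and keeps the strand. The labels describe the ddm1 library as paired-end and the other libraries as strand-specific, and the design text calls all of them paired-end.

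Per the submitters' processing notes, Trim Galore 0.3.3, TopHat2 and Cufflinks were used; the versions of TopHat2 and Cufflinks and their options are not given in the sources used here. The notes list TAIR10 as the genome build for all 4 samples, so the builds used for rice and maize are not given in the sources used here. Per the series design, each sample contains 3 biological replicates, and how they were combined into 1 assembly is not stated. The deposited Arabidopsis and rice assemblies give for each transcript its exons, its FPKM (fragments scaled to transcript length and library size), a 95% lower and upper bound of the FPKM and a mean coverage, all as Cufflinks wrote them. The deposited score of each transcript ranks it within its locus and was not used here. The deposited maize assembly holds transcript structures with merged identifiers and no FPKM, so no maize transcript has an abundance here. All transcripts in the 4 assemblies are named by assembly identifiers; none carries a gene name.

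The Arabidopsis transcripts were placed on the TAIR10.1 reference, whose 5 nuclear chromosomes carry 37899 annotated genes. Of the distinct introns assembled, 97.6% in wild type and 96.3% in ddm1 coincide with an annotated intron, and 98.7% in each library have GT and AG at their ends in that sequence. A transcript of at least 200 nt was assigned to the gene on its strand that holds the largest share of its exonic bases, with a share of at least 0.5. A transcript without a strand could be assigned to a gene on either strand. Gene FPKM is the sum over the gene's transcripts. The ratio is log2((FPKM in ddm1 + 1)/(FPKM in wild type + 1)), so ratios of weakly expressed genes are understated. A gene counts as higher or lower by size when its log2 ratio is at least 1 in absolute value and its FPKM is at least 1 in either library.

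Summing counts a gene more than once when its transcript is broken into pieces, each with its own FPKM, and a gene joined to a neighbour in 1 long transcript receives no value when most of that transcript lies on the neighbour. Therefore a second value, the exon-averaged FPKM, was computed: the FPKM of every overlapping transcript on the strand, weighted by its overlap, divided by the length of the gene's annotated exons. Intact genes are those with 1 cluster of transcripts in each library that covers at least 50% of the exons and is not joined to a neighbour. The second value, the intact genes, the ranking of genes among them and the 200 nt minimum for gene values were chosen after the data were examined. The main value, the size rule, the gene lists, the naming rule and most alternatives were fixed before the data were examined.

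The reference does not mark transposable element genes. The annotation's category pseudogene, with 3917 genes, was used in their place; it also contains pseudogenes of other gene families. Lower-case sequence in the reference does not separate them, with a median of 8.87% of exonic bases in pseudogenes and 10.1% in protein-coding genes, so it was not used as a measure of repeats. The pericentromere was taken as 3 Mb on either side of rounded centromere positions (15, 4, 14, 4 and 12 Mb on chromosomes 1 to 5), which is 25.2% of the nuclear genome. An intergenic transcript is at least 200 nt long and overlaps no annotated gene on either strand. At least 1 lower-case base lay in 56 of 57 intergenic loci of wild type and 606 of 663 of ddm1. The median share of exonic bases in lower case was 20.4% in wild type and 16.7% in ddm1. No annotation of rice or maize was used, so genes, gene lists and intergenic transcripts of those species are not analysed here. Chloroplast and mitochondrial transcripts were left out of the gene values.

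Named genes are DDM1; the 12 genes of highest and the 12 of lowest ratio; the 8 pseudogenes of highest ratio; up to 4 members of each list, those of largest absolute ratio; and the 3 intergenic loci of highest FPKM per library. The 8 loci of highest FPKM were planned for rice and maize by gene name; without an annotation the leading rice loci are named by position. Other list members named in the text were chosen after their values were seen. Each of the 14 Arabidopsis lists was compared with 10000 random lists of equal size, drawn from genes in the same of 20 bins of mean expression, and its percentile describes these libraries.

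There was 1 assembly per group (n = 1), so no test, p-value, SD or check across replicates was possible and differences are described by size alone. The bounds cover the uncertainty Cufflinks assigned within a library and not the variation between plants. Read totals were not used because the assemblies hold none; instead the width of the FPKM bounds was converted to fragments, and the library size follows from transcripts of at least 2000 nt that are alone at their locus. This added estimate gave medians of 58.6 M fragments (M, 1000000) for wild type Arabidopsis (interquartile range 57.6 to 59.7, 3507 transcripts), 74.7 M for ddm1 (73.7 to 76.0, 3443 transcripts) and 147 M for rice (143 to 150.5, 4392 transcripts). The median half-width of the bounds was 9.59%, 12.3% and 12.3% of the FPKM in these libraries.

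On simulated data with 200 changed genes among 18136, the size rule found 52 of 67 genes changed 2.5-fold, 66 of 67 changed 4-fold and 64 of 66 changed 8-fold, and took up 0 of 17936 unchanged genes. The simulated library was the wild type with small random noise. It held no split or joined genes, no missing transcripts, no scale shift and no variation between plants. The 0 of 17936 follows from that setting and says nothing of false calls in the real libraries. All 2000 transcripts built from annotated exons returned to their gene, and 0 of 2000 were taken as intergenic. Of 200 unshifted simulated lists, 11 fell outside the central 95% of random lists, and all 50 lists shifted by 1.5 lay above it.

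Alternatives changed the pseudocount (0.1), the scaling (division by the median ratio, or FPKM rescaled to a fixed total as TPM), the gene value (its most abundant transcript), the FPKM minimum, the fold and the rules for intergenic transcripts. For the TPM rescaling, transcripts under 200 nt were left out of the totals, a choice made after the data were examined: a single 49 nt transcript carries an FPKM of 7821690 in wild type. Division by the median ratio of 0.895 moves the median of all genes by 0.16, and the TPM rescaling moves it by -0.08. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.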

Results

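Transcripts were assembled from seedlings of Arabidopsis, rice and maize and from an Arabidopsis mutant of DDM1, a chromatin remodeller that maintains DNA methylation and the silencing of transposable elements. Per its title, the series concerns stress-related intergenic long noncoding RNAs that arise from transposable elements. Each of the 4 groups had 1 assembly (n = 1), so every difference given here is a difference in size between single libraries, with no replicate check and no p-value. The library sizes implied by the FPKM bounds were 58.6 M fragments for wild type Arabidopsis, 74.7 M for ddm1 and 147 M for rice (M, 1000000), and the depth of the maize library is unknown.

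The assemblies differed in the long introns of their transcripts. Maize had 3788 introns of at least 5000 nt, 2.80% of its distinct introns, against 706 (0.590%) in rice, 12 (0.0114%) in wild type Arabidopsis and 35 (0.0365%) in ddm1. The median intron measured 153 nt in maize, 164 nt in rice and 101 nt in each Arabidopsis library. Wild type Arabidopsis had 26843 transcripts at 20632 loci, ddm1 34993 at 30303, rice 42727 at 29976 and maize 45217 at 31785. Rice loci overlapped a locus of the opposite strand most often (10.3%), followed by maize (6.67%), wild type Arabidopsis (6.30%) and ddm1 (3.92%). Transcripts without a strand, 1258 in ddm1 and 5 in wild type Arabidopsis, could not enter such overlaps. The share of single-exon transcripts was 16.1% in wild type Arabidopsis, 28.9% in ddm1, 25.9% in rice and 21.7% in maize. Among rice transcripts of at least 200 nt the highest FPKM lay at chromosome 12, 4506639 to 4507609 (1827), chromosome 1, 17349053 to 17350587 (1743) and chromosome 1, 32708679 to 32709614 (1668), in the coordinates of the deposited assembly. The assemblies were built on different genomes with unequal depth, so these values describe each assembly and set no order between the species.

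**Figure D1:**
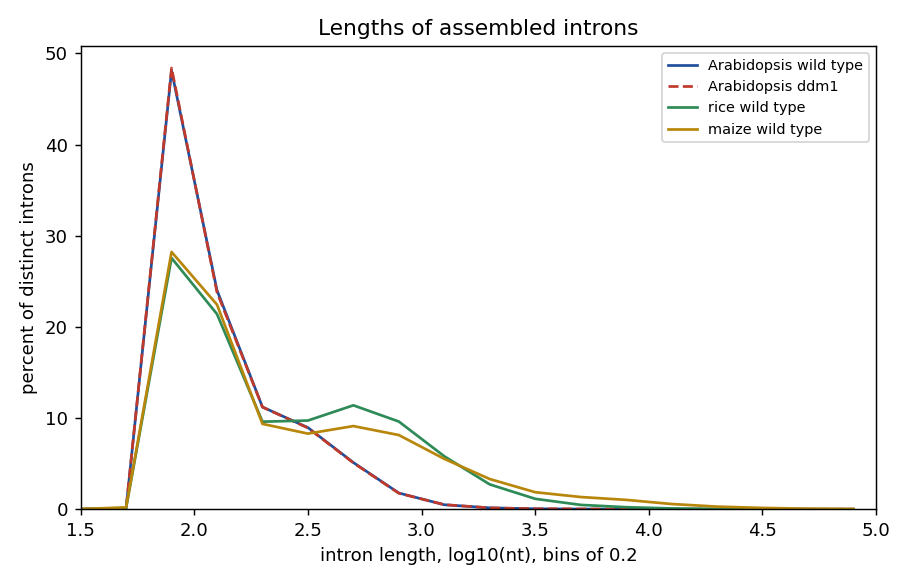
Lengths of the distinct introns in the 4 assemblies, on a log10 scale of nucleotides in bins of 0.2, as a percent of each assembly's introns. The curves of wild type and ddm1 Arabidopsis overlie each other, and rice and maize carry a tail of longer introns, with 0.590% and 2.80% of introns at 5000 nt or more.

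DDM1 (AT5G66750, chromosome 5, 26648897 to 26653191, plus strand) was represented by a single transcript of 16 exons in wild type, at 26648928 to 26652999, with an FPKM of 4.28 (bounds 3.94 to 4.62). In ddm1 the gene was covered by 3 shorter transcripts with FPKM of 0.517, 0.787 and 0.499, the first at 26649795 to 26651064 and the others within 26651191 to 26652706. Their sum, 1.80, gave a log2 ratio of -0.91, just under the size rule, and the exon-averaged FPKM gave -1.71, past it. Both values place DDM1 lower in the library labelled ddm1.

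Transcripts from annotated pseudogenes, the category that stands here for transposable element genes, were far more frequent in ddm1. Of 3917 annotated pseudogenes, 77 had an FPKM of at least 1 in wild type and 1309 in ddm1; at an FPKM of at least 10 the numbers were 22 and 429. By size, 1249 pseudogenes were higher in ddm1 and 17 lower. Wild type had no transcript overlapping 1207 of the 1309. The 8 of highest ratio were all listed at 0 in wild type. AT3G42650 (chromosome 3, 14739356 to 14741466) reached an FPKM of 595 in ddm1 and AT5G32490 552.5. They were followed by AT1G36260 (538), AT2G04770 (494), AT1G36190 (386), AT3G43867 (342), AT1G42410 (318) and AT5G28785 (307). All 8 also passed the size rule by exon-averaged FPKM, in another order. AT5G28785 was then highest (426), while AT5G32490 had 138, AT1G42410 68.9 and AT3G43867 51.8. Transcripts covered 25.1% of the exons of AT5G32490 and 15.2% of those of AT3G43867.

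The pericentromeric regions, where transposable elements of Arabidopsis are densest, held most of these pseudogenes. There, 1111 of 3290 pseudogenes had an FPKM of at least 1 in ddm1 against 40 in wild type, and 1080 were higher by size and 9 lower. On the arms, 198 of 627 passed that level in ddm1 against 37 in wild type, with 169 higher and 8 lower. As a share of the pseudogenes annotated in each region, 32.8% were higher in the pericentromere and 27.0% on the arms. The median FPKM of pseudogenes at 1 or more was 5.18 in ddm1, against 11.3 for protein-coding genes of that library.

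Few pseudogenes had a transcript in each library, and among these 30 were higher in ddm1 and 12 lower (71.4% higher); of the intact ones 6 were higher and 5 lower. The highest ratio was that of AT4G04293 (chromosome 4, 2076832 to 2077361), which went from an FPKM of 1.202 to 317, a log2 ratio of 7.17. AT2G04460 followed with 4.53, AT5G34790 with 4.32, AT1G25430 with 3.62, AT4G08115 with 3.55, AT2G07080 with 3.09, the extensin pseudogene EXT11 with 2.97 and AT2G13975 with 2.69. With exon-averaged FPKM, 1047 pseudogenes were higher and 22 lower, and AT4G08115 went from 3.55 to 0.94, below the size rule. The ddm1 assembly held 1258 transcripts without a strand and wild type 5; from transcripts with a strand alone, 1247 pseudogenes were higher and 17 lower. From multi-exon transcripts alone the numbers were 554 and 17, and of the transcripts assigned to pseudogenes 62.3% had 1 exon in ddm1 and 54.1% in wild type. Pseudogenes that are near-identical copies share reads, and the value of a single copy is uncertain.

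**Figure D2:**
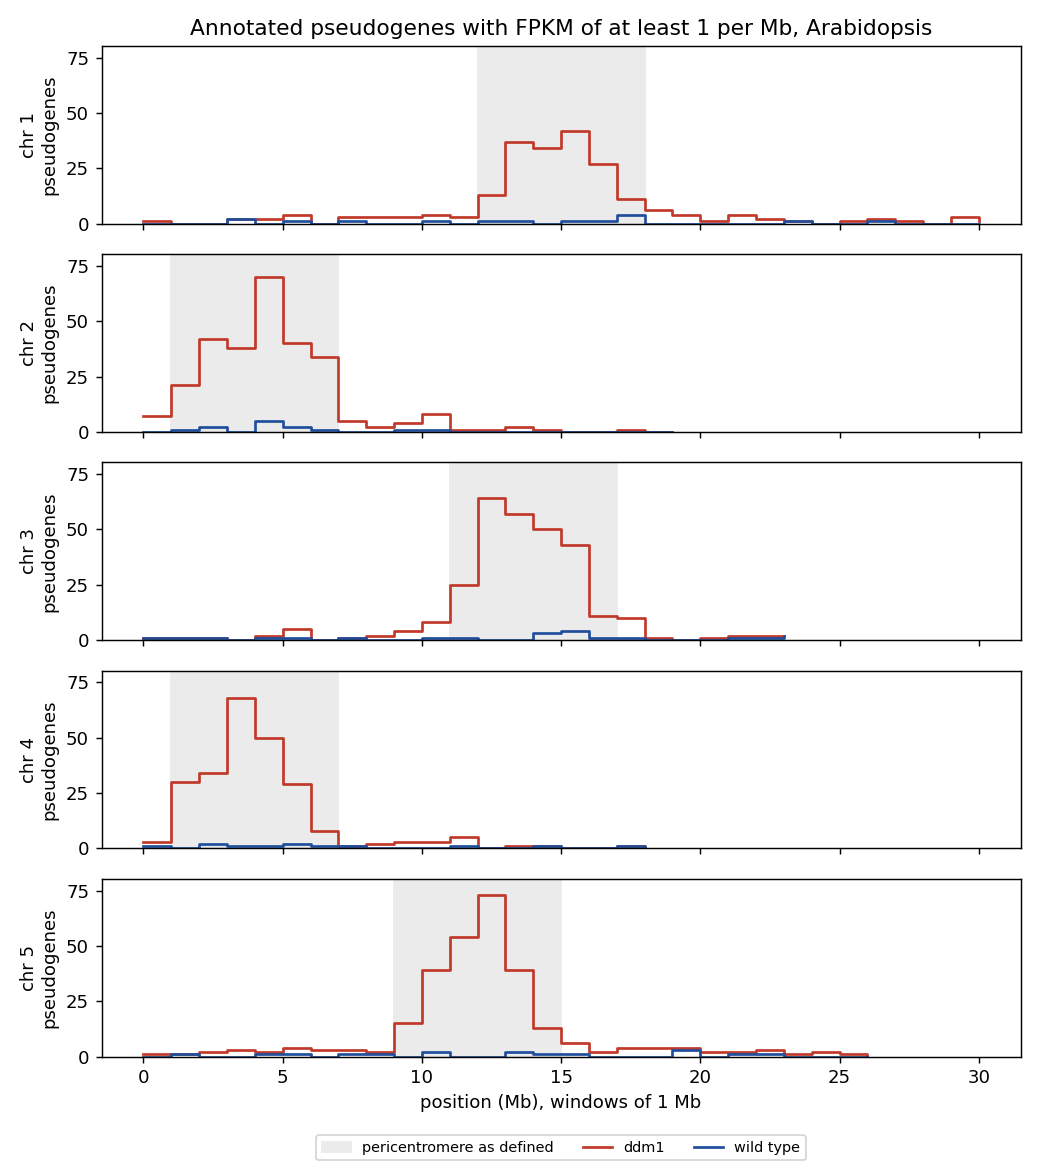
Number of annotated pseudogenes with an FPKM of at least 1 in windows of 1 Mb along the 5 Arabidopsis chromosomes, wild type in blue and ddm1 in red, with the pericentromere shaded. The window with the most, at 12 Mb on chromosome 5, held 73 in ddm1 and 0 in wild type among 186 annotated.

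Over all annotated genes, 5312 were higher in ddm1 and 3049 lower by summed FPKM, so that 63.5% of the differences were toward ddm1; after division by the median ratio the numbers were 5934 and 2477 (70.6%). Protein-coding genes made up 3828 of those higher and 2903 of those lower. With exon-averaged FPKM 2560 genes were higher and 3850 lower (39.9%), and from multi-exon transcripts alone 3121 and 3059 (50.5%). The exon-averaged counts went with a shift of the whole distribution, since the median log2 ratio of genes at 1 or more in each library was -0.35 by that measure and -0.14 by summed FPKM; after division by its own median ratio (0.752) the exon-averaged numbers were 3631 and 2317 (61.0%). Restricting the genes leaves out those without a transcript in 1 library, of which 2804 were higher and 381 lower: among the 19001 genes with a transcript in each, 2508 were higher and 2668 lower (48.5%), and among the 12424 intact genes, whose median was -0.32, 697 and 2054 (25.3%). By both measures together, 1070 protein-coding genes were higher and 2334 lower. In ddm1 4689 genes were covered by separate pieces against 345 in wild type, while 1177 wild type transcripts joined neighbouring genes against 411 in ddm1. Of the 2804 higher genes with no wild type transcript assigned, 873 were overlapped by one.

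**Figure D3:**
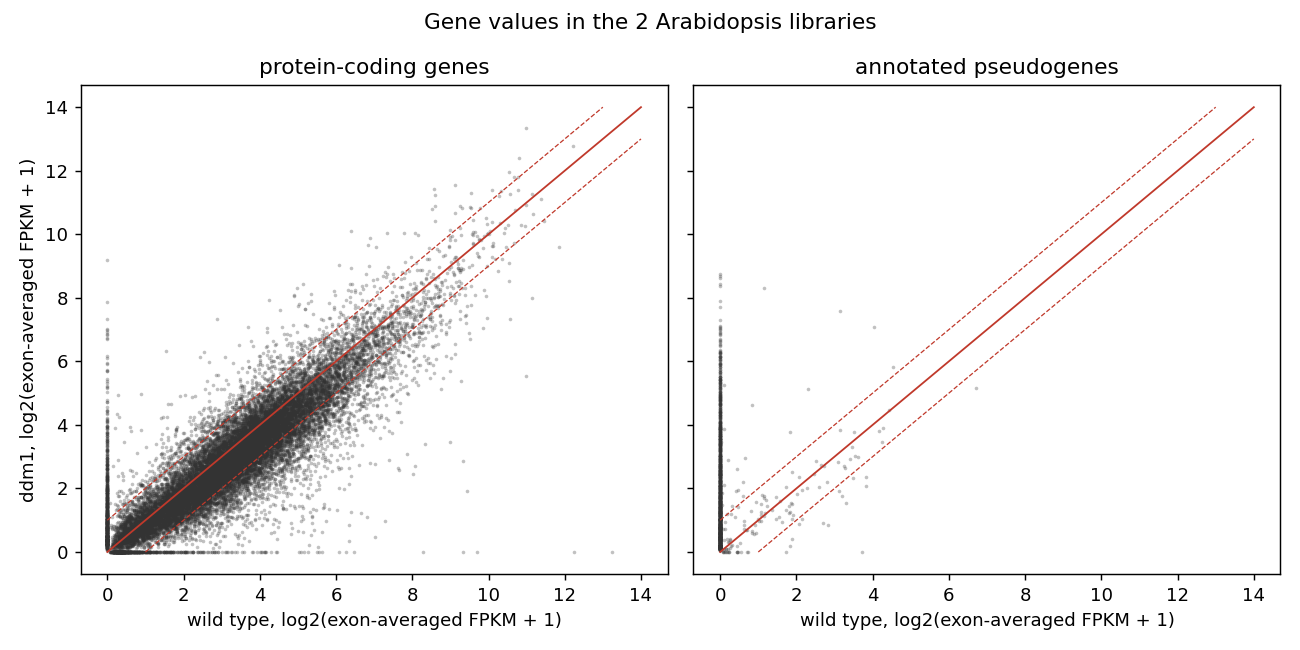
Exon-averaged FPKM of each gene in wild type (x axis) and ddm1 (y axis), both as log2(value + 1), for protein-coding genes (left) and annotated pseudogenes (right). The solid line marks equal values and the dashed lines a log2 ratio of 1 in either direction; protein-coding genes lie along the line with 1258 higher and 3496 lower, and pseudogenes lie mostly on the axis of wild type 0 with 1047 higher and 22 lower.

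The 12 genes of lowest ratio were listed at 0 in ddm1, led by RBCS1A, a small subunit of Rubisco, with a wild type FPKM of 13459 (chromosome 1, 25048158 to 25049667), and by LHCB1.3, a light-harvesting protein of photosystem II, with 4935. LHCB1.2 (1075), LHCB4.1 (974), LHCB1.1 (837), the photosystem I gene PSAD-2 (674) and the NDH subunit gene PnsL1 (169) were also among them, as were AT2G25210 (1081), AT1G51200 (411), AT3G08520 (384), AKR2 (224) and SEC61 BETA (207). RBCS1A, the 3 LHCB1 genes, AT1G51200 and AT3G08520 had no transcript in ddm1, whereas the others were overlapped by one assigned to a neighbour or to no gene. By exon-averaged FPKM, LHCB4.1 (0.43) and PSAD-2 (2.72) were not lower in ddm1, and PnsL1 (-0.72) did not pass the size rule. An FPKM of 0 for such abundant genes can be a failed assembly and is given only as listed.

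The 12 genes of highest ratio were listed at 0 in wild type. They were PDE334, of the chloroplast ATP synthase, with an FPKM of 2105 in ddm1, the plastid ribosomal protein gene RPL12-C (1867), the photosystem II gene PSBX (1010), AT4G40030 (747), AT1G59930 (618), the plastid ribosomal protein gene RPL15 (604), the peroxisomal malate dehydrogenase gene PMDH2 (589), AT5G65220 (561), the ubiquitin gene UBQ1 (506) and the pseudogenes AT3G42650, AT5G32490 and AT1G36260 given above. AT1G59930 (chromosome 1, 22060924 to 22061516) and the pseudogenes had no wild type transcript. The other 8 were overlapped in wild type by a transcript assigned to a neighbour or to no gene, and their exon-averaged log2 ratios lay between 0.47 (PMDH2) and 2.55 (RPL12-C); PMDH2, PSBX (0.70) and RPL15 (0.96) did not pass the size rule by that measure.

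Intact genes, neither split into separate clusters nor joined to a neighbour by the rule above, gave log2 ratios up to 7.17 and down to -5.68. Overlapping partial transcripts are still summed in them: the intact gene DML2 gave -1.17 by summed and -0.22 by exon-averaged FPKM. After the pseudogene AT4G04293, the largest increases were in AG605 (5.34), a noncoding locus silenced by methylation, AT3G29639 (4.71), AT2G00430 (4.70), AT5G26270 (4.68), AT4G15150 (4.25), AT1G77960 (4.07), AT3G22142 (3.71), the pollen coat oleosin gene GRP19 (3.66), AT5G28230 (3.50), the mitochondrial dicarboxylate carrier gene DIC2 (3.32) and the cold-response regulator CBF2 (3.30). AT5G26270 went from an FPKM of 8.60 to 245. The largest decreases were in the noncoding RNA gene AT5G07322, from 158 to 2.09, in AT1G76960 (-5.67), AT3G23390 (-5.40), AT1G34418 (-5.20), AT2G40205 (-5.15), the flavonol synthase gene FLS1 (-4.84), the defensin gene PDF2.1 (-4.17), AT1G79220 (-4.11), RVE2 (-4.11), AT2G20724 (-4.11), RHA2A (-3.93) and the light-harvesting gene LHCB4.3 (-3.92). These intact genes were chosen after the values were seen.

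Most measured loci known to be silenced by DNA methylation were higher in ddm1 by summed FPKM. Of the 11 loci in this list 9 were measured, and 8 were higher and none lower. ATGP1 and ONSEN had no transcript in either library. AG605 went from an FPKM of 5.29 to 254 and SDC, an F-box gene silenced by promoter methylation, from 0.439 to 13.9 (log2 ratio 3.37). FWA reached 3.75 and the Mutator-like element ATMU1 3.12 in ddm1, each with no transcript in wild type; by exon-averaged FPKM FWA (0.91) no longer passed the size rule. The median log2 ratio of 1.92 lay at percentile 99.9 of random lists, and with exon-averaged FPKM 3 were higher and 2 lower of 6 measured (median 1.27, percentile 99.9). BNS, a locus that gains methylation over generations without DDM1, was among the lower 2, with -1.18, against -0.72 by summed FPKM. The other was COPIA4 (-1.73), which is among the 8 higher by summed FPKM and was joined to a neighbour in wild type.

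Genes of the methylation machinery did not move together. Of 14 genes for DNA methylation and demethylation, 3 were higher (CMT3, VIM1 and DML3) and 1 lower (DML2), with a median of 0.40 at percentile 90.5. The chromomethylase gene CMT3 went from 8.84 to 56.4 (log2 ratio 2.55), DML3 gave 1.53, VIM1 1.07 and the demethylase gene DML2 -1.17. Of 22 genes for RNA-directed methylation and small RNAs, 6 were higher and none lower (median 0.38, percentile 93.6), led by AGO6 (3.19), SHH1 (1.87), NRPD1 (1.41) and NRPE1 (1.298). All 9 higher genes of these groups were split in ddm1, and with exon-averaged FPKM none of them passed the size rule; CMT3 (-0.13), DML3 (-0.05) and NRPE1 (-0.11) then changed sign. By that measure none of 13 methylation genes differed, and of the 22 only KTF1 (-1.18) did, with medians of -0.22 (percentile 72.6) and -0.23 (percentile 68.2).

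In the list of DDM1 and chromatin remodelling, 3 of 5 histone genes were lower in ddm1. The histone H2A.W gene HTA7 went from 77.1 to 19.3 (log2 ratio -1.94), and the linker histone genes H1.1 and H1.2 gave -1.23 and -1.22. These 3 intact genes were lower by either measure, and under each scaling of summed FPKM. By exon-averaged FPKM H1.1 gave -1.05, where the median of all genes was -0.35, so that call may rest on scale. Among all intact genes 697 were higher and 2054 lower. The other H2A.W genes of the list, HTA6 (-0.10) and HTA12 (0.41), did not pass the size rule. MOM1, a silencing factor, gave 1.03 and, with exon-averaged FPKM, 0.15. Of the 12 genes 1 was higher and 3 lower, and the list median of -0.41 lay at percentile 10.3; with exon-averaged FPKM 4 were lower, DDM1 being the fourth, and the median was -0.67 (percentile 6.89).

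Most genes of cold, drought and abscisic acid response passed the size rule in neither direction. The transcription factor genes CBF2 (log2 ratio 3.30), CBF1 (2.69) and CBF3 (1.38) were higher in ddm1, and the cold-induced genes KIN2, from 1023 to 16.6 (log2 ratio -5.86), KIN1 (-4.91) and COR15B (-1.66) were lower, by either measure. The cold-induced genes COR15A (-0.97), RD29A (-0.10), COR47 (0.04) and ERD10 (0.84) did not pass. Of the 22 genes of this list 4 were higher, 3 lower and 15 neither, with a median of -0.25 at percentile 26.9, and with exon-averaged FPKM 3 and 4 (median -0.40, percentile 38.0). KIN1 and KIN2 are near-identical neighbours, so their separate values are uncertain. Clock genes differed in the same libraries: CCA1 (1.61) and PRR5 (1.38) were higher, PRR9 reached 3.09 in ddm1 and was listed at 0 in wild type, and ELF4 (-2.17) and GRP7 (-1.31) were lower. In the clock list 5 of 13 genes were higher and 2 lower (median 0.29, percentile 75.9), and 3 and 2 of 11 with exon-averaged FPKM (median 0.67, percentile 99.9). The hour of harvest is not given in the sources used here.

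Immune genes showed few differences. Of 25 genes of salicylic acid and immune response, 5 were higher and 2 lower (median 0.19, percentile 83.6). The lower 2 were PAD4 (-1.27) and PR1 (-1.23), whose exon-averaged log2 ratios of 0.01 and -0.56 did not pass the size rule. The transcription factor gene WRKY33 went from 23.6 to 78.6 (log2 ratio 1.69), and WRKY53 reached 6.44 in ddm1 with no wild type transcript; only these 2 passed the size rule with exon-averaged FPKM, which gave a median of -0.03 (percentile 96.7). ICS1, the salicylic acid synthesis gene, had 1.55 and then 0.10, and the resistance gene RPP4, listed at 0 in wild type, had 17.3 in ddm1 and an exon-averaged log2 ratio of 0.20. Among heat shock genes 2 of 8 measured were higher, HSP90.1 (14.5 in ddm1) and HSP18.2 (2.17), both listed at 0 in wild type; HSP90.1 was joined to a neighbour there and gave an exon-averaged log2 ratio of 0.50, below the size rule. HSP17.4 gave -0.72 and HSP17.6A -0.52 (list median 0.28, percentile 32.3; exon-averaged -0.16, percentile 53.1). Among 13 DNA damage genes PARP2 (1.86), BRCA1 (1.27) and RAD17 (1.77 in ddm1, listed at 0 in wild type) were higher and SMR4 gave -0.73, with a median of -0.35 at percentile 5.58; exon-averaged, BRCA1 gave -0.18 and only RAD17 was higher (median -0.39, percentile 21.9).

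Several light-harvesting genes outside the LHCB1 cluster were higher in ddm1. LHCB2.2 (log2 ratio 2.88), LHCB2.1 (2.27), the photosystem I gene PSAD1 (2.23), LHCA1 (1.60), LHCA2 (1.303) and LHCB3 (1.06) passed the size rule, and LHCB3 did not with exon-averaged FPKM (0.92). Of 18 photosynthesis genes measured 6 were higher and 5 lower, the latter being RBCS1A, LHCB1.1, LHCB1.2, LHCB1.3 and LHCB4.1. With exon-averaged FPKM 6 of 19 were higher, PSBP1 (1.27) in place of LHCB3, and 4 lower, without LHCB4.1 (0.43). The median of 0.27 lay at percentile 94.7, and at 0.41 and percentile 99.8 with exon-averaged FPKM. RBCS1B, RBCS2B and RBCS3B were listed at 0 in each library, and LHCB2.1 and LHCB2.2 are near-identical neighbours whose separate values are uncertain.

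Markers of other tissues and reference genes give the background of the comparison. All 4 measured seed storage genes were higher in ddm1 by either measure: the cruciferin genes CRC (log2 ratio 2.31) and CRA1 (2.09), the albumin gene SESA1 (1.24) and the oleosin gene OLEO1, at 2.42 in ddm1 and listed at 0 in wild type. Their median of 1.93 lay at percentile 95.2, and the exon-averaged median of 1.68 at percentile 98.6. Of 12 root markers NRT2.1 (1.52) and PLT1 (1.18) were higher, IRT1 gave -0.73 and CASP1 -0.71 (median 0.14, percentile 51.99); exon-averaged, the first 2 no longer passed and IRT1 (-1.89) and CASP1 (-1.10) were lower (median -0.11, percentile 76.0). Of 7 flowering genes measured SEP3 (1.65) and AG, at 1.32 in ddm1 and listed at 0 in wild type, were higher, AG no longer with exon-averaged FPKM (0.38), FT gave 0.80 and SOC1 0.21 (median 0.21, percentile 47.4; exon-averaged 0.12, percentile 86.5). Of 13 reference genes UBC21 (2.07) was higher, UBQ5 (-1.51) and ACT7 (-1.16) were lower and TUB2 gave 0.75, with a median of 0.13 at percentile 82.4 (exon-averaged 0.06, percentile 92.4). With exon-averaged FPKM UBC21 gave 0.40, and none of the 13 was higher and 3 were lower, UBQ5, ACT7 and PP2AA3 (-1.07, against -0.11 by summed FPKM). ACT7 gave -0.999, just short of the size rule, after division by the median ratio.

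**Figure D4:**
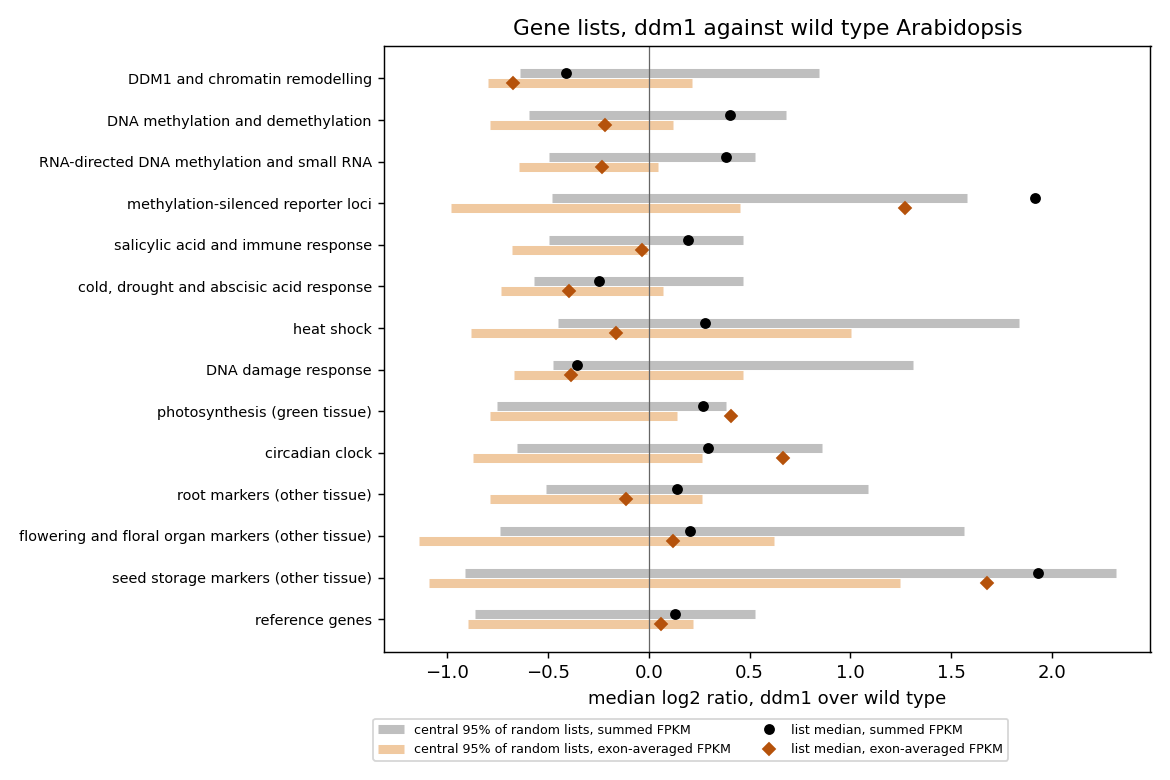
Median log2 ratio of each gene list, ddm1 over wild type, by summed FPKM (black circles) and exon-averaged FPKM (orange diamonds), with bars for the central 95% of 10000 random lists matched on expression. The methylation-silenced loci lie above their bars by both measures (1.92 and 1.27), and seed storage, clock and photosynthesis genes lie above theirs by exon-averaged FPKM (1.68, 0.67 and 0.41).

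Intergenic transcription was concentrated in the pericentromeres of ddm1. Outside annotated genes, ddm1 had 680 transcripts at 663 loci, 559 of them in the pericentromere and 104 on the arms, against 57 in wild type, 16 in the pericentromere and 41 on the arms. Of the ddm1 loci 631 overlapped no intergenic locus of wild type, 547 of them pericentromeric, and 32 did; a wild type transcript of any kind overlapped 59 of the 663. Of the wild type loci 29 overlapped one of ddm1. At an FPKM of at least 1 there were 492 intergenic transcripts in ddm1 and 22 in wild type.

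The strongest intergenic locus of ddm1 was a spliced transcript of 2 exons and 208 nt on chromosome 5, 11194021 to 11194302 (plus strand), with an FPKM of 554. It was followed by single-exon transcripts without a strand on chromosome 4, 3416175 to 3418075 (275), 188 nt from AT4G06548, and on chromosome 1, 21456348 to 21457565 (244), 102 nt from AT1G58025; no wild type transcript overlapped any of the 3. In wild type the loci of highest FPKM were on chromosome 3, 12559455 to 12560071 (minus strand, 2 exons, FPKM 101), chromosome 5, 10018902 to 10019213 (12.99) and chromosome 2, 10075621 to 10075992 (11.7). Most intergenic transcripts had 1 exon, 581 in ddm1 and 50 in wild type, and 525 intergenic transcripts of ddm1 carried no strand against none in wild type. With multi-exon transcripts alone the numbers were 99 and 7. The ratio between the libraries was smaller for transcripts that carry a strand (155 in ddm1 and 57 in wild type), when only genes on the same strand counted as overlapping (764 and 165) and when the annotation was limited to protein-coding genes and pseudogenes (1129 and 483).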

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

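The 3 results in this part were noticed after the data were examined, and none was tested. They concern transcripts outside the gene comparisons, with more in ddm1 than in wild type Arabidopsis. The ddm1 assembly held 11 chloroplast transcripts, and the wild type assembly held 0. It held 77 mitochondrial transcripts against 28 in wild type. Transcripts under 200 nt, which were left out of the gene values, numbered 316 in ddm1 and 79 in wild type.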

How the results depend on the processing

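The alternatives named as exon-averaged FPKM (also divided by its own median ratio), genes with a transcript in both libraries, intact genes, transcripts of any length, a share of 0.8, the annotation without noncoding genes, transcripts with a strand and, for gene values, multi-exon transcripts were chosen after the results were seen. Of the counts, 101 stayed within 1.5 times under an alternative and 45 did not; the cause was not tested except where stated. Annotated genes higher in ddm1 numbered 2354 and lower 701 at 4-fold; higher genes numbered 2560 by exon-averaged FPKM, 2508 with a transcript in both libraries and 697 if intact, the last 2 being smaller sets by construction, and 3121 from multi-exon transcripts. Protein-coding genes gave 1394 higher and 645 lower at 4-fold, and 1258, 2415, 665 and 2467 higher in those 4 alternatives; lower ones numbered 2948 from multi-exon transcripts, more than the higher ones, and exon-averaged FPKM divided by its own median ratio gave 2177 higher and 2016 lower. Pseudogenes higher in ddm1 numbered 640 at an FPKM of at least 5, 30 with a transcript in both libraries and 6 if intact, since few have a wild type transcript, and 554 from multi-exon transcripts; lower ones numbered 5 at 4-fold and 5 if intact. At an FPKM of at least 5, 33 pseudogenes were present in wild type and 662 in ddm1, and at 1 from multi-exon transcripts 38 and 576. Pseudogenes higher in ddm1 outnumbered lower ones in every alternative run. Leaving out transcripts without a strand moved no gene count by over 1.5 times. Intergenic transcripts of wild type numbered 35 at 500 nt, 22 at an FPKM of at least 1, 7 if multi-exon, 27 at 500 nt from any gene, 165 with same-strand overlap only and 483 against protein-coding genes and pseudogenes alone; those of ddm1 numbered 301 at 500 nt, 99 if multi-exon, 378 at 500 nt from any gene, 1129 against that annotation and 155 with a strand. Shared loci of wild type were 9 at 500 nt, 12 at an FPKM of at least 1, 2 if multi-exon, 15 at 500 nt from genes and 3 on the same strand, and those of ddm1 8, 13, 2, 16 and 3. Rice had 25354 transcripts at an FPKM of at least 1. Of list medians 68 moved by less than the spread of their random lists; 2 moved more, RNA-directed methylation to -0.23 by exon-averaged FPKM and the methylation-silenced loci to 4.70 with a pseudocount of 0.1, which most affects loci listed at 0. Of the named genes with a transcript in each library 251 values moved by less than their bounds, 104 moved and 5 changed sign: CMT3 (-0.13), DML3 (-0.049), NRPE1 (-0.11) and BRCA1 (-0.18) by exon-averaged FPKM, and DML2 (0.081) by its most abundant transcript. Of those listed at 0 in ddm1, PSAD-2 (2.72) and LHCB4.1 (0.43) were not lower by exon-averaged FPKM, and COPIA4, listed at 0 in wild type, gave -1.73. Leaving out the FPKM minimum moved nothing by construction, since a log2 ratio of 1 already requires an FPKM of at least 1. No paired analysis was possible because each group had 1 assembly, and none could be left out. Depth limits weak loci: the bounds lay a median of 9.59% of the FPKM to either side in wild type and 12.3% in ddm1.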

Other observations

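In this part the tests of deeper sampling, of fragmented assembly, of split or joined genes, of very high read number, of shared reads in RBCS1A and the LHCB1 genes, and of transcripts without a strand were chosen after the results were seen; the tests of shared reads in repeated elements and of scale were set before.

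Light-harvesting genes outside the fixed lists are added here. LHB1B2 (AT2G34420, chromosome 2, 14522524 to 14523568), of the same LHCB1 family as the genes listed at 0 in ddm1, had an FPKM of 2021 in wild type and 12788 in ddm1, a log2 ratio of 2.66. Its neighbour LHB1B1 had 379 and 1370, a log2 ratio of 1.85. Their exon-averaged log2 ratios were 2.39 and 1.98. LHCB4.3 (AT2G40100), an intact gene of that chromosome, gave -3.92, while LHCB2.1 and LHCB2.2, also on chromosome 2 and in the fixed list, gave 2.27 and 2.88. LHB1B1, LHB1B2 and LHCB4.3 were chosen after their values were seen.

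Transcribed pseudogenes and lncRNA genes were counted beside all annotated genes, for which 63.5% of the differences were toward ddm1 by summed and 39.9% by exon-averaged FPKM. Of transcribed pseudogenes 68 were higher in ddm1 and 25 lower (73.1%), and 50 and 34 (59.5%) with exon-averaged FPKM. Of annotated lncRNA genes 82 were higher and 39 lower (67.8%), and 119 and 63 (65.4%) with exon-averaged FPKM. Antisense transcripts, with no gene on their own strand, numbered 84 in ddm1 and 108 in wild type. Transcripts without a strand, 1258 in ddm1 and 5 in wild type, have no own strand and could be assigned to a gene on either. These antisense counts are therefore not comparable between the libraries. Protein-coding genes higher by both measures made up 5.13% of those annotated in the pericentromere and 3.74% of those on the arms.

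Pseudogenes with transcripts in ddm1 were weighed against deeper sampling, transcripts without a strand, fragmented assembly and reads shared between copies. With ddm1 scaled to the wild type library size, 998 pseudogenes had at least 100 implied fragments against 67 in wild type. That is 14.9 times as many, which argues against depth as the whole cause. From transcripts with a strand alone 1307 passed an FPKM of 1 against 77, 17.0 times as many. The count thus did not rest on transcripts without a strand. Such transcripts were rare on annotated genes, with 153 of 5505 single-exon transcripts on intronless genes in ddm1. The filter could therefore remove little, and it does not weigh other differences between the assemblies. At an exon-averaged FPKM of at least 1 the number of pseudogenes was 13.6 times that of wild type. This argues against pieces counted more than once as the whole cause. The number of protein-coding genes was 0.985 times that of wild type, a quotient of 13.8. The quotient decides little, because protein-coding genes at 1 or more had a median FPKM of 11.3 in ddm1 and 13.5 in wild type. Their count at that level could hardly respond to fragmentation. Among the 1426 pseudogenes with at least 90% unique 31-mers, 409 passed an FPKM of 1 in ddm1 and 58 in wild type, a ratio of 7.05 that argues against shared reads as the whole cause, although in the 1102 with under 50% unique 31-mers the numbers were 404 and 3. The hypothesis that loss of DDM1 function may release these pseudogenes stays open: genotype and library are confounded with 1 assembly each, and the labels describe the libraries differently.

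The excess of protein-coding genes higher in ddm1 by summed FPKM could come from the form of the assemblies. Of the 2323 such genes that were split in ddm1 or joined to a neighbour in wild type, 9.60% were still higher with exon-averaged FPKM, against 56.3% of the other 1505, so that most of the calls among split or joined genes ended when pieces were averaged over the gene. Averaging lowers split genes by construction and counts exons without a transcript as 0. The loss of a call therefore does not show which value is nearer the true level. A difference of scale is argued against as the whole cause: the median log2 ratio of genes at an FPKM of at least 1 in each library was -0.14, so division by the median ratio widened the excess, to 4401 higher and 2336 lower. The TPM rescaling narrowed it, from 3828 higher and 2903 lower to 3724 and 3365, without ending it. With exon-averaged FPKM 1258 protein-coding genes were higher and 3496 lower, and 2177 and 2016 after division by its own median ratio. The excess was thus smaller at the same scaling, and the direction without that division depended on scale. Unequal coverage of exons may add to this shift and was not tested. An effect of genotype stays open, untested.

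RBCS1A and the 3 LHCB1 genes were among the 100 most abundant genes of wild type by implied fragments and had no transcript in ddm1. In the next 900 genes 0 lacked one. RBCS1B, RBCS2B and RBCS3B had no transcript in either library, so RBCS genes without a transcript were not confined to ddm1. Their true levels are unknown here, and this does not settle the cause. Shared reads are argued against for RBCS1A, with 97.4% unique exonic 31-mers, and stay open for the LHCB1 genes, with 67.9% to 74.9%. A limit on reads per locus in assembly may apply and was tested at the wild type level and the ddm1 library size. RBCS1A would hold 108% of the highest implied fragments of 1 transcript in ddm1, and the LHCB1 genes together 74.5%. That maximum belonged to LHB1B2, itself of the LHCB1 family. Since shared reads stay open for the LHCB1 genes, the maximum may be too high. Implied fragments can also fall far short, so the maximum may instead be too low. The ddm1 locus at chromosome 1, 7142944 to 7146276, with an FPKM of 10010 and a longest transcript of 1845 nt, was given 4637. The ranking of the wild type genes has the same limit. The test therefore cannot place these genes inside or past the range, and the explanation stays open. This test replaced an earlier one, the count given first (4 of the top 100 against 0 of the next 900), which had gone with the explanation but ran on the genes that define the pattern. An effect of genotype also stays open, untested.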
